A study of Arabidopsis thaliana with 6 samples.

How the data were processed

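The data are RNA-seq of 6 inflorescence libraries, 3 treated with DMSO and 3 with DEX, and groups and replicate numbers were taken from the labels. TopHat and HTSeq were used, per the submitters' processing notes, and their versions and settings, the genome build and the use of strand are not given in the sources used here. The deposited values are reads per 1000000 reads (RPM) for 17675 genes, scaled so that each library has the same total over the listed genes. Each listed gene has at least 1 RPM in 3 or more libraries, as the values show, so weaker genes were not analysed here. A gene that meets this minimum through 1 group alone is listed because of that group, which favours genes that differ. Because RPM values of each library are whole multiples of the value of 1 read, reads could be recovered: 100% of the values came out whole within 0.01 reads in all 6 libraries. Recovered totals over the listed genes were 10703769 to 14469527 reads per library, so 1 read equals 0.0691 to 0.0934 RPM and 3 reads equal 0.207 to 0.280 RPM. Intervals and floors from reads cover counting error only. Reads without strand cannot separate a gene from an antisense or overlapping partner, and near-identical copies may exchange reads.

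Gene names were taken from a RefSeq annotation of TAIR10.1, which matched 17646 identifiers and did not match 29, of which 16 end in Ler_0_iso1. The annotation was used only for names, exon length and GC content. No coordinates are given, since the build of the deposited table is not stated.

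Before the data were examined, the test, the 23 gene lists, the rule for named genes and the alternatives were fixed. RPM were converted to log2(RPM + 1), which understates the change of weakly expressed genes, and tested with limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The planned filter of at least 1 RPM in 3 libraries removed no gene. Gene lists with at least 3 measured members were tested with camera, a competitive test, at a preset correlation of 0.01 between genes and adjusted over the 23 lists, and again with an estimated correlation and with fry. The preset-correlation calls of 9 lists are each lost with an estimated correlation. Of 361 list members 303 were in the table. After the genes with the largest changes had been seen, 11 further lists were written down before their own values were looked at, and they were adjusted among themselves. Nothing says that the replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. The 3 libraries of each group differed by more than sampling noise (chi-square per degree of freedom of 2.80 to 12.0), so none was counted as a repeat. Treatment duration, harvest time and batch are not given in the sources used here.

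The rule for named genes takes the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of at least 5 RPM in the higher group and no overlap between the groups. It also takes up to 4 members of each fixed list past the threshold, by size of change, or the 2 members of smallest p where none passes. It further takes, whatever their result, ARF3, WUS, CLV3, STM, KNU, CRC, LOG3, LOG4, LOG7, AHK4, ARR5, ARR7 and ARR15, and AGAMOUS, IPT3, IPT5 and IPT7, which were not analysed here. Members named outside this rule, to spell out a small count, as examples of genes that did not pass or from the added lists, were chosen after their values were seen. The values of 1 gene that the rule takes are not reported here.

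The procedure was tested on simulated counts with the means and library sizes of these samples, over 17675 genes. In this simulation of DEX against DMSO, limma recovered 49.3% of 67 genes changed by 1.5-fold, 86.6% of 67 changed by 2-fold and 98.5% of 66 changed by 4-fold, and 10 unchanged genes (6.02% of the calls) were called. The simulation changed far fewer genes than the 10204 called in the data, and the adjusted threshold depends on that share. Its rates of recovered and false calls therefore need not hold for these data. Alternatives were other pseudocounts (0.1 and 5), a minimum of 5 RPM or no minimum, median-of-ratios and TMM scaling, limma without the trend or with robust moderation, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, a log2 fold change of at least 1, and leaving out each library. The edgeR test called 10146 genes. List counts without DEX-3 were added after seeing that this library stands apart, and those without each other library were added later still.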

Results

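RNA-seq was carried out on inflorescences of Arabidopsis thaliana plants that carry ARF3:ARF3-GR in the arf3-29 mutant background. ARF3 is an auxin response factor, and GR is the hormone-binding domain of the glucocorticoid receptor, which holds a fused protein inactive until a steroid such as dexamethasone (DEX) is given. Plants 3 weeks old, grown at 23 °C with 16 h of light and 8 h of dark, received either 10 µM DEX in DMSO or DMSO alone, both with 0.015% of the wetting agent Silwet. Only flowers of stage 6 and younger were kept. There were 3 libraries per treatment. Reads of the listed genes, as recovered from the RPM, were 12437315, 13645763 and 12655222 for DMSO and 10703769, 14469527 and 14290693 for DEX. The comparison asks which genes respond when ARF3-GR is activated in the young flower, where the study relates ARF3, AGAMOUS and auxin to cytokinin and to the end of stem cell activity in the floral meristem. All 6 libraries share a genotype, and DEX-treated plants without ARF3-GR were not analysed here, so a response to DEX itself and a response to ARF3-GR enter the same difference. Levels are given in reads per 1000000 reads (RPM) as mean ± SD over n = 3 libraries, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

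DEX libraries had far more RNA of genes known to be induced by darkness or sugar shortage, and less RNA of flavonoid and cell wall genes. ASN1 (AT3G47340), an asparagine synthetase, rose from 13.7 ± 0.209 RPM to 917 ± 49.2 RPM, a log2 fold change of 5.97 (SE 0.0690, adjusted p = 1.75e-19). SEN1 (AT4G35770), a gene of dark-treated and ageing leaves, rose from 18.1 ± 0.338 to 963 ± 90.0 RPM (log2 fold change 5.65, SE 0.0746, adjusted p = 8.06e-19). BCAT-2 (AT1G10070), a branched-chain aminotransferase, rose from 3.2 ± 0.669 to 145 ± 11 RPM. At the other end, AT4G28780 fell from 46.1 ± 3.31 to 4.03 ± 1.03 RPM (log2 fold change -3.25, SE 0.152, adjusted p = 7.15e-12), and the expansin EXPA6 (AT2G28950) fell from 414 ± 11.5 to 65.3 ± 5.04 RPM.

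The other genes with the highest log2 fold changes were GLYI7 (AT1G80160, 5.26), RAP2.6 (AT1G43160, 5.18), DIN11 (AT3G49620, 4.88), AT2G05540 (4.75), AT2G32150 (4.66), GLYI4 (AT1G15380, 4.54) and J8 (AT1G80920, 4.23). The other genes with the lowest were AT5G52390 (-2.73), AT1G67750 (-2.61), UGT78D3 (AT5G17030, -2.57), FLS1 (AT5G08640, -2.55), AT1G15760 (-2.55), CHS (AT5G13930, -2.50), 4CL3 (AT1G65060, -2.49) and GH9C2 (AT1G64390, -2.48). Of 17675 genes tested, 10204 (57.7%) passed an adjusted p of 0.05 (limma), 5238 higher and 4966 lower in DEX. Of these, 1563 were higher and 924 were lower by at least 1 on the log2 scale, and the median absolute log2 fold change of the 10204 genes was 0.65. With 57.7% of all genes past the threshold, a count at or below that share does not set a gene list apart. The 3 DEX values all lay above or all below the 3 DMSO values for 11116 genes (62.9%), where chance gives 10%. Across genes, Spearman correlations were 0.991 within DMSO and between DEX-1 and DEX-2, 0.985 and 0.987 between DEX-3 and the other DEX libraries, and 0.905 to 0.914 between treatments. Reads of ribosomal RNA genes took 1.67 ± 0.362% of the DMSO libraries and 2.51 ± 0.411% of the DEX libraries, with the highest share, 2.96%, in DEX-3.

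**Figure D1:**
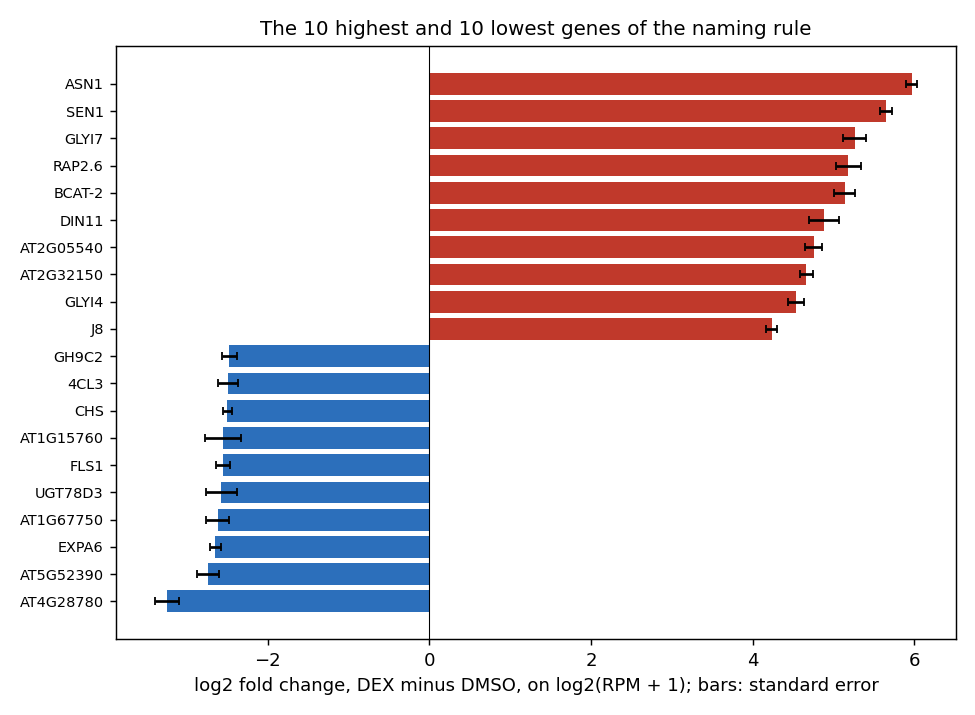
Log2 fold changes, DEX minus DMSO on log2(RPM + 1), of the 10 highest and 10 lowest genes of the naming rule, with bars showing the standard error (n = 3 libraries per treatment). The rises reach 5.97 in ASN1, while the lowest value is -3.25 in AT4G28780.

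ARF3 RNA (AT2G33860) was present in every library and fell from 248 ± 8.64 to 144 ± 4.14 RPM with DEX (log2 fold change -0.77, SE 0.0624, limma adjusted p = 1.15e-08). These reads can come from the transgene and from the arf3-29 allele alike. WUS (AT2G17950), the regulator of stem cell fate, had 4.10 ± 0.646 RPM in DMSO and 2.83 ± 1.70 RPM in DEX, a difference of -0.50 that did not pass the test (95% interval -1.06 to 0.06, limma adjusted p = 0.116). Without DEX-1 the WUS difference was -0.83 (adjusted p = 0.00781), and without DEX-3 it was -0.19 (adjusted p = 0.512), these being the lowest and highest adjusted p with 1 library left out. CLV3 (AT2G27250), the stem cell signal, had 2.55 ± 0.723 and 2.58 ± 1.27 RPM, with an interval of the log2 difference from -0.56 to 0.51. STM (AT1G62360), needed to maintain the meristem, fell from 138 ± 7.87 to 106 ± 17.9 RPM (log2 fold change -0.39, limma adjusted p = 0.00285), or by 0.24 on the log2 scale without DEX-3. KNU (AT5G14010), a repressor of WUS, fell from 3.28 ± 0.621 to 1.87 ± 0.571 RPM (limma adjusted p = 0.0315). Its adjusted p was 0.128 without DEX-1, 0.0602 without DEX-2, 0.129 without DMSO-2, 0.0647 without DMSO-3 and 0.0573 with DESeq2. CRC (AT1G69180), a carpel gene, rose from 95.8 ± 9.37 to 123 ± 22.5 RPM (limma adjusted p = 0.0131), with an adjusted p of 0.0907 without DMSO-1, 0.0918 without DEX-2 and 0.0951 in limma without the intensity trend. Of 21 meristem genes 9 fell and 2 rose, and the same numbers passed when adjusted over the list alone. PAN (AT1G68640), an activator of AGAMOUS, fell from 19.3 ± 3.08 to 10.2 ± 1.29 RPM, HAM2 (AT3G60630) fell from 70.3 ± 2.07 to 42.7 ± 3.1 RPM, and KNAT6 (AT1G23380) and CRC were the 2 that rose, KNAT6 from 13.7 ± 2.59 to 26.5 ± 3.96 RPM. The list as a whole did not stand apart from other genes (median -0.13, camera adjusted p = 0.164). AGAMOUS was not analysed here.

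**Figure D2:**
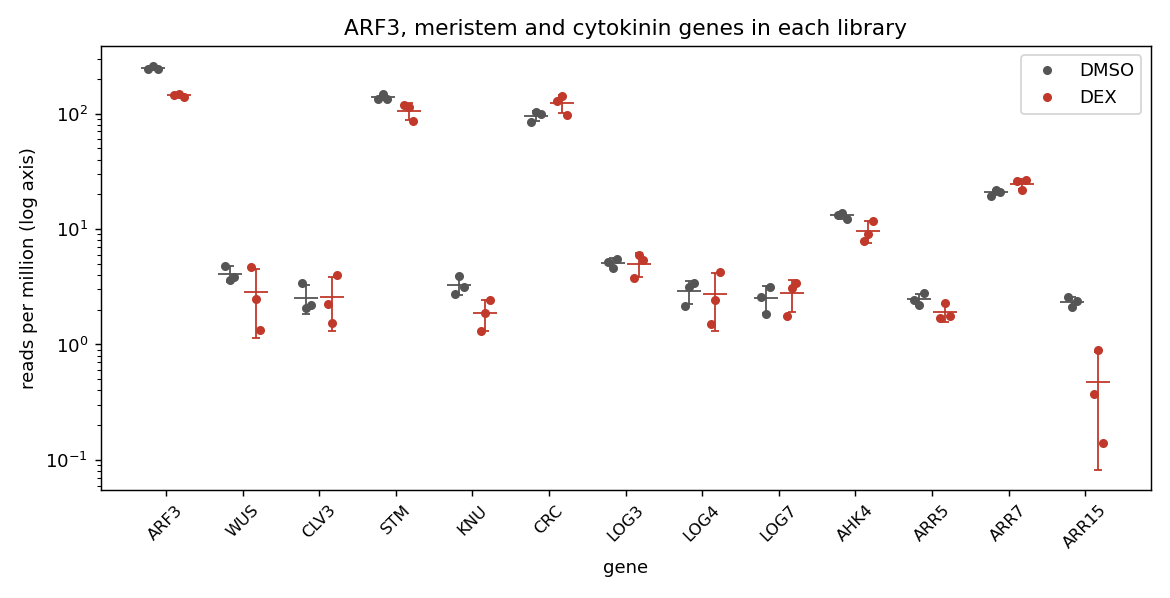
RPM on a log axis of ARF3, meristem genes and cytokinin genes in each of the 3 DMSO and 3 DEX libraries, with horizontal lines at the mean and bars showing the SD. ARF3 lies near 248 RPM in DMSO and 144 RPM in DEX, ARR15 near 2.36 and 0.471 RPM, while the WUS values of the treatments overlap.

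Cytokinin genes moved both ways. Of 9 measured biosynthesis genes, 3 LOG genes rose and IPT9 (AT5G20040) fell, with the same counts adjusted over the list alone (median 0.09, camera adjusted p = 0.381). The LOG enzymes release active cytokinin. LOG5 (AT4G35190) rose from 94.4 ± 4.19 to 279 ± 3.14 RPM (log2 fold change 1.55, SE 0.0639, limma adjusted p = 1.28e-12), LOG1 (AT2G28305) from 9.76 ± 0.603 to 14.5 ± 0.815 RPM and LOG8 (AT5G11950) from 20.4 ± 1.41 to 28.4 ± 2.54 RPM. The fall of IPT9 was -0.35 on the log2 scale (limma adjusted p = 0.0130) and did not pass without DEX-2 (adjusted p = 0.0755). LOG3 (AT2G37210), LOG4 (AT3G53450) and LOG7 (AT5G06300) had log2 differences of -0.03, -0.12 and 0.09, with 95% intervals of -0.44 to 0.37, -0.66 to 0.42 and -0.41 to 0.58. IPT3, IPT5 and IPT7 were not analysed here.

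In cytokinin perception and relay, 5 of 14 genes rose and 2 fell, as they did adjusted over the list alone (median 0.23, camera adjusted p = 0.431). The receptor AHK3 (AT1G27320) rose from 21.3 ± 2.23 to 40.9 ± 2.46 RPM and the response regulator ARR1 (AT3G16857) from 95.4 ± 2.65 to 141 ± 6.77 RPM, together with the phosphotransfer genes AHP2 (AT3G29350), AHP5 (AT1G03430) and AHP3 (AT5G39340). The call of AHP3 had an adjusted p of 0.0269, against 0.0904 without DEX-1, 0.0504 without DEX-2, 0.102 without DMSO-2 and 0.0637 without DMSO-3. ARR10 (AT4G31920) and the receptor AHK4 (AT2G01830) fell, AHK4 from 13.1 ± 0.820 to 9.63 ± 1.99 RPM (limma adjusted p = 0.0255). The adjusted p of AHK4 was 0.117 without DEX-1, 0.0688 without DEX-2, 0.0696 without DMSO-1 and 0.0847 without DMSO-2. Of the 9 type-A response regulators, which cytokinin induces, ARR15 (AT1G74890) fell from 2.36 ± 0.224 to 0.471 ± 0.388 RPM (log2 fold change -1.22, SE 0.246, limma adjusted p = 0.000415). ARR3 (AT1G59940) rose from 0.260 ± 0.205 to 1.85 ± 0.281 RPM, both counts being the same adjusted over the list alone (median 0.18, camera adjusted p = 0.993). ARR3 reaches 1 RPM in no DMSO library and ARR15 in no DEX library. Both are thus weakly expressed and in the table because of 1 group, which favours such changes. The other 7 did not pass, among them ARR5 (AT3G48100, -0.25, 95% interval -0.70 to 0.19) and ARR7 (AT1G19050, 0.24, interval -0.004 to 0.48). ARR7 passed without DEX-2, at 0.33 (adjusted p = 0.0350). Of the 5 cytokinin oxidases, which degrade the hormone, CKX5 (AT1G75450), CKX7 (AT5G21482) and CKX6 (AT3G63440) fell, CKX7 from 39.4 ± 5.47 to 21.3 ± 1.64 RPM. CKX3 (AT5G56970) and CKX4 (AT4G29740) rose, CKX3 from 2.57 ± 0.587 to 5.74 ± 0.966 RPM, with the same counts adjusted over the list alone (median -0.84, camera adjusted p = 0.473).

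More Aux/IAA and GH3 genes rose than fell in DEX, and more genes of auxin synthesis and transport fell than rose. Of 20 Aux/IAA genes, early targets of auxin, 11 rose and 5 fell, also adjusted over the list alone (median 0.47, camera adjusted p = 0.0960). IAA2 (AT3G23030) rose from 6.97 ± 0.744 to 40.6 ± 7.10 RPM and IAA4 (AT5G43700) from 12.1 ± 0.767 to 51.3 ± 5.88 RPM. The 5 that fell were IAA17, IAA32, IAA27, IAA9 and IAA8, of which IAA8 did not pass without DEX-2 (adjusted p = 0.0760), without DMSO-3 (adjusted p = 0.0506) or in limma without the intensity trend (adjusted p = 0.0987). Of 8 GH3 and SAUR genes GH3.5, GH3.2, GH3.6 and GH3.3 rose and GH3.17 (AT1G28130) fell, while neither of the 2 SAUR genes passed, also adjusted over the list alone (median 0.34, camera adjusted p = 0.170), with GH3.5 (AT4G27260) rising from 202 ± 9.42 to 497 ± 42.0 RPM and GH3.2 (AT4G37390) from 40.4 ± 3.49 to 77.2 ± 2.81 RPM. Of 17 genes of auxin synthesis, transport and perception 8 fell and 2 rose, also adjusted over the list alone (median -0.20, camera adjusted p = 0.0697, and 0.0396 without DEX-3). The influx carrier LAX2 (AT2G21050) fell from 148 ± 9.76 to 53.8 ± 7.43 RPM, and the kinase PID (AT2G34650) from 108 ± 4.57 to 54.7 ± 4.46 RPM. TAR2 and LAX3 were the 2 that rose.

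Several other auxin response factors fell along with ARF3. Of 14 measured, 7 fell and ARF2 rose, also adjusted over the list alone (median -0.32, camera adjusted p = 0.0190, and adjusted p = 0.420 with an estimated correlation). ARF4 (AT5G60450), a close relative of ARF3, fell from 149 ± 8.54 to 62.4 ± 2.46 RPM, and ARF5 (AT1G19850) from 208 ± 4.37 to 113 ± 3.18 RPM. The call of ARF2, a log2 fold change of 0.21 (adjusted p = 0.0113), did not pass without DMSO-1 (adjusted p = 0.0531) or in limma without the intensity trend (adjusted p = 0.0808). Of 14 organ polarity genes 9 fell and KAN1 rose, also adjusted over the list alone (median -0.53, camera adjusted p = 0.0140, and adjusted p = 0.420 with an estimated correlation). HB8 (AT4G32880) fell from 30.6 ± 1.33 to 15 ± 1.47 RPM and PHV (AT1G30490) from 103 ± 1.92 to 59.6 ± 2.97 RPM, both of the family that marks the upper side of organs. FIL (AT2G45190), of the lower side, fell from 249 ± 9.40 to 157 ± 28.5 RPM. The rise of KAN1 (adjusted p = 0.0440) passed in all 6 libraries and without DEX-3, where it was 0.70, but not without any other library. Its adjusted p was 0.296 without DEX-1, 0.10 without DEX-2, 0.122 without DMSO-1, 0.0651 without DMSO-2, 0.122 without DMSO-3, 0.133 in limma without the intensity trend and 0.0685 with robust moderation.

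Genes of organ identity moved both ways, each by less than 1 on the log2 scale. Of 18 measured, 7 rose and 4 fell (7 and 5 adjusted over the list alone), with a median of -0.08, a mean of 0.03 and a camera test pointing up (adjusted p = 0.820), so the signs differ. PI (AT5G20240), needed for petals and stamens, rose from 173 ± 6.16 to 268 ± 7.33 RPM, and SOC1 (AT2G45660) from 24.1 ± 3.47 to 37.0 ± 4.30 RPM. CAL (AT1G26310) fell from 14.8 ± 0.442 to 9.31 ± 1.46 RPM. The other 3 that fell were AP2, AGL6 and AP3, of which AP3 had an adjusted p of 0.0209, against 0.0889 without DMSO-2, 0.0678 without DMSO-3 and 0.118 in limma without the intensity trend, and a log2 fold change of -0.23, against -0.13 without DEX-3. Of 10 gynoecium genes, SPT (AT4G36930) rose from 68.0 ± 2.0 to 90.5 ± 7.13 RPM, NGA1 (AT2G46870) rose and STY1 (AT3G51060) fell from 18.0 ± 1.47 to 9.78 ± 1.41 RPM, also adjusted over the list alone (median -0.13, camera adjusted p = 0.820). The NGA1 adjusted p was 0.0236, against 0.0571 without DEX-1, 0.0863 without DEX-2 and 0.102 without DMSO-1. Without DEX-2 1 gynoecium gene rose and 2 fell, NGA3 (AT1G01030) also passing at -0.57 (adjusted p = 0.0281).

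Most cell cycle, cell wall and flavonoid genes fell. Of 26 cell cycle genes 21 fell and none rose (20 and 1 without DEX-2), also adjusted over the list alone (median -0.69, camera adjusted p = 4.71e-07, and adjusted p = 0.0759 with an estimated correlation). The DNA replication genes fell most, PCNA1 (AT1G07370) from 146 ± 10.2 to 27.0 ± 4.94 RPM and MCM7 (AT4G02060) from 89.8 ± 4.01 to 25.2 ± 2.70 RPM. PCNA1 and PCNA2 (AT2G29570) are near-identical, so the division of reads between them is uncertain. Of 16 expansin and xyloglucan genes, which loosen the cell wall, 10 fell and XTH24 rose, also adjusted over the list alone (median -0.84, camera adjusted p = 0.000587, and adjusted p = 0.259 with an estimated correlation). EXPA15 (AT2G03090) fell from 550 ± 24.0 to 125 ± 7.80 RPM and EXPA5 (AT3G29030) from 39.8 ± 1.86 to 7.66 ± 0.481 RPM. Of 9 flavonoid genes 8 fell, also adjusted over the list alone (median -1.57, camera adjusted p = 7.52e-06, and adjusted p = 0.0764 with an estimated correlation). CHS, the first enzyme of the pathway, fell from 1436 ± 44.6 to 254 ± 3.86 RPM and FLS1 from 254 ± 15.6 to 42.6 ± 5.62 RPM, while the regulator PAP1 had 1.98 ± 1.18 and 2.19 ± 0.456 RPM and did not pass. Of 9 gibberellin genes 4 fell and 2 rose (5 and 2 adjusted over the list alone, median -0.32, camera adjusted p = 0.286). GASA4 (AT5G15230) fell from 341 ± 14.5 to 148 ± 3.11 RPM and GA3OX1 (AT1G15550), a synthesis enzyme, from 9.60 ± 2.35 to 4.29 ± 0.822 RPM, while GA2OX6 (AT1G02400), which inactivates gibberellin, rose from 0.824 ± 0.0871 to 3.95 ± 0.741 RPM. GA2OX6 reaches 1 RPM in no DMSO library and so is in the table because of its DEX values, which favours genes that rose. GAI and GA20OX1 (AT4G25420) also fell and GA2OX2 rose. The adjusted p of GA20OX1 was 0.0377, against 0.0616 without DEX-1, 0.10 without DEX-2, 0.130 without DMSO-1, 0.101 without DMSO-2 and 0.0601 with DESeq2, and that of GA2OX2 was 0.0301, against 0.146 without DEX-1, 0.0615 without DMSO-1 and 0.104 without DMSO-3.

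Genes of touch, wounding and jasmonate were mostly higher in DEX. Of 23, 14 rose and 4 fell (15 and 4 adjusted over the list alone, median 0.67, camera adjusted p = 0.0179, and adjusted p = 0.255 with an estimated correlation). TCH3 (AT2G41100), a calmodulin-like gene, rose from 139 ± 4.38 to 846 ± 2.45 RPM, WRKY40 (AT1G80840) from 7.94 ± 1.53 to 55.7 ± 1.99 RPM and ZAT10 (AT1G27730) from 13.4 ± 1.95 to 72.9 ± 6.72 RPM. The 4 that fell were TCH2, LOX2, VSP1 and VSP2, the last 3 being jasmonate synthesis or response genes. Of 9 heat shock genes 6 rose (7, with 1 that fell, without DEX-2), also adjusted over the list alone (median 0.90, camera adjusted p = 0.0196, and adjusted p = 0.437 with an estimated correlation), with HSP90.1 (AT5G52640) rising from 41.3 ± 8.27 to 141 ± 11.6 RPM and HSP70-4 (AT3G12580) from 145 ± 21.5 to 346 ± 4.91 RPM. Of 8 salicylic acid and defence genes PR5 (AT1G75040), EDS5 (AT4G39030), EDS1 (AT3G48090) and PAD4 (AT3G52430) rose, also adjusted over the list alone (median 0.29, camera adjusted p = 0.193), PR5 from 44.9 ± 4.65 to 141 ± 3.16 RPM. PAD4 had an adjusted p of 0.0160, against 0.0743 without DEX-1 and 0.0670 without DMSO-3. Of 16 clock genes 11 rose and GI fell (12 and 1 adjusted over the list alone, median 0.43, camera adjusted p = 0.0216, and adjusted p = 0.259 with an estimated correlation). Only 6 rose without DMSO-1, where CCA1, ELF3, LUX, PRR9 and TOC1 did not pass, and 7 without DEX-2, where CCA1, ELF3, LUX and TOC1 did not, with 8 to 10 without any other library. RVE1 (AT5G17300) rose from 2.54 ± 0.654 to 13.3 ± 2.39 RPM and PRR7 (AT5G02810) from 19.7 ± 0.616 to 44.8 ± 2.30 RPM, whereas LHY, a core clock gene, had 4.37 ± 0.935 and 4.64 ± 0.699 RPM and did not pass.

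Markers of other tissues also differed between the treatments. Of 17 anther, tapetum and pollen wall genes 7 were in the table, and all 7 rose, also adjusted over the list alone (median 1.07, camera adjusted p = 0.0190, and adjusted p = 0.259 with an estimated correlation). Of the 7, 5 reach 1 RPM in fewer than 3 DMSO libraries and so are in the table because of their DEX values, which favours genes that rose. ATA7 (AT4G28395) rose from 0.401 ± 0.370 to 4.49 ± 1.02 RPM and ACOS5 (AT1G62940) from 0.943 ± 0.712 to 3.39 ± 0.288 RPM. CYP703A2 (AT1G01280) had 0 reads in the 3 DMSO libraries and 2.02 ± 0.373 RPM in DEX, which is at least 26.1-fold higher, against a floor of 3 reads over the DMSO group. CYP703A2 already lies above the list median of 1.07, so setting it to its bound could not move that median. Without DEX-3, 6 of the 7 rose, LAP6 (AT1G02050) having an adjusted p of 0.0298 in all libraries and 0.0985 without DEX-3. Its adjusted p was 0.0504 without DEX-2, 0.0607 without DMSO-1, 0.161 without DMSO-3 and 0.0629 in limma without the intensity trend. A list of meiosis genes, chosen later, had a median of -0.56 over its 4 measured members. Of 11 green tissue genes 5 rose (CAB2, LHCB4.2, CAB1, RCA and RBCS1A) and 3 fell, also adjusted over the list alone (median 0.17, camera adjusted p = 0.457). CAB2 (AT1G29920) rose from 297 ± 21.1 to 482 ± 12.1 RPM and RBCS1B (AT5G38430) fell from 130 ± 3.67 to 92.1 ± 9.98 RPM, in families whose near-identical copies make single members uncertain. The other 2 that fell were RBCS2B and LHCB2.2 (AT2G05070), the latter with an adjusted p of 0.0112, against 0.0702 without DMSO-1, 0.0751 without DMSO-3, 0.0982 in limma without the intensity trend, 0.155 with robust moderation and 0.148 with DESeq2. The rise of RBCS1A (adjusted p = 0.00478) did not pass without the trend either (adjusted p = 0.0716). Of 10 xylem genes XCP1 (AT4G35350), CESA4 (AT5G44030), IRX9 (AT2G37090) and CESA7 (AT5G17420) fell (3 of them adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.286). XCP1 fell from 7.61 ± 0.973 to 3.35 ± 1.53 RPM. CESA7 did not pass without DMSO-2 (adjusted p = 0.0742), nor IRX9 without DEX-1 (0.0592), DEX-2 (0.136), DMSO-1 (0.0865) or DMSO-3 (0.132), with a pseudocount of 5 (0.0502) or with DESeq2 (0.0592). Without DEX-1 3 xylem genes fell and 1 rose, XCP2 (AT1G20850) passing at 0.35 (adjusted p = 0.0446).

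DEX-3, which stood apart and had the highest rRNA share, moved some of these counts. Without it the counts that rose and fell were 6 and 2 for cytokinin perception, 2 and 1 for type-A response regulators, 10 and 6 for Aux/IAA genes, 3 and 8 for auxin synthesis and transport, and 2 and 8 for meristem genes. They were 7 and 6 for floral identity, 2 and 10 for expansins, 10 and 1 for the clock, and 6 and 4 for green tissue, and the 13 lists not named here or among the anther markers kept their counts. Other libraries moved counts too, to 4 and 1 for cytokinin perception without DEX-1 or DEX-2, 10 and 4 for Aux/IAA genes without DMSO-3, 1 and 7 for meristem genes without DMSO-1, 5 and 3 for floral identity without DMSO-3, and 0 and 18 for the cell cycle without DMSO-1.

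**Figure D3:**
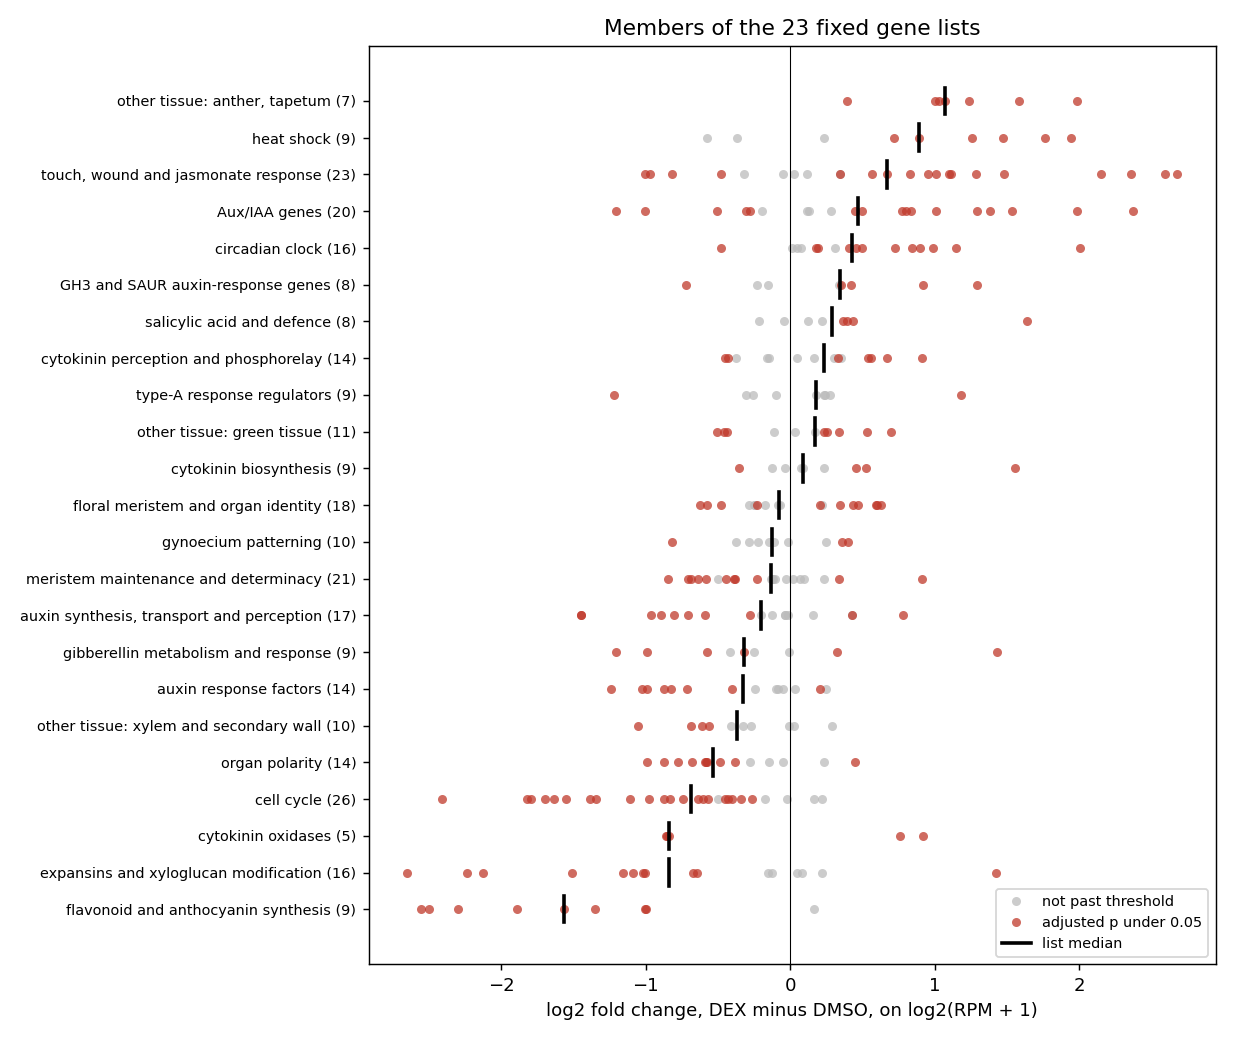
Log2 fold change, DEX minus DMSO on log2(RPM + 1), of each measured member of the 23 fixed gene lists, with measured members in brackets, members past an adjusted p of 0.05 in red, others in grey, and a black bar at the list median. Medians run from -1.57 in the flavonoid list to 1.07 in the anther list.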

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

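The list counts without DEX-3 and without each other library were chosen after seeing the data, and the other alternatives were planned. Of 16 clock genes 12 passed, 7 without DMSO-1, 8 without DEX-2 and 9 to 11 without any other library, and the other fixed lists kept their totals within 1.5-fold. Between 9072 and 10412 genes passed when 1 library was left out (higher 4711 to 5336, lower 4323 to 5076). The total was 10127 and 10250 with pseudocounts of 0.1 and 5, 10215 with median-of-ratios scaling, 10210 with TMM, 9662 without the trend, 10213 with robust moderation, 10146 with edgeR and 9691 with DESeq2. With a minimum of 5 RPM, 9141 of 14447 genes passed, and dropping the minimum moved nothing, since the table already meets it. No gene called in all 6 libraries changed sign under these settings. Requiring a log2 fold change of at least 1 leaves 2487 genes, 1563 higher and 924 lower, by its construction. The replicate numbers showed no shared effect, and whether the samples were paired is not given in the sources used here. Deviations of same-numbered libraries correlated at -0.0471, 0.0622 and 0.0291, and DMSO-1 correlated best with DEX-3. A replicate block called 10255 genes, with 98.8% of the calls kept in the same direction. ARF3 passed throughout, at -0.79 to -0.75 without 1 library. For the other 117 named genes, 1932 of 1971 values kept their side of the threshold and direction, 37 lost the call, 2 gained one (WUS without DEX-1, ARR7 without DEX-2) and none reversed. The cause was not tested. With an estimated correlation the adjusted p was 0.420 for auxin response factors and for organ polarity, 0.0759 for cell cycle, 0.259 for expansins, clock and anther genes, 0.0764 for flavonoid, 0.255 for touch and wound and 0.437 for heat shock genes. By its construction fry does not compare a list with other genes, and it gave adjusted p of 0.0129 for cytokinin biosynthesis, 0.000639 for perception, 0.00309 for Aux/IAA, 0.00194 for GH3 and SAUR and for salicylic acid, 0.000498 for auxin synthesis and transport, 0.00397 for meristem, 0.00450 for gibberellin, 0.0237 for green tissue and 0.00594 for xylem genes. Type-A response regulators (fry adjusted p = 0.343), cytokinin oxidases (0.0518), floral identity (0.307) and gynoecium genes (0.420) did not pass. The auxin synthesis and transport list ranged from 0.0396 (without DEX-3) to 0.0805 when 1 library was left out.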

Other observations

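The tests of scaling and of time of day and the random lists matched on 2 features were chosen after the result was seen, and the other tests were written down before theirs were. The added lists were chosen after the genes with the largest changes had been seen.

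Genes of carbon shortage rose as a group in DEX. In a list of low-sugar inducible genes that holds none of the genes seen first, all 13 measured rose (median log2 fold change 2.44, camera adjusted p = 6.87e-13, and adjusted p = 0.0149 with an estimated correlation). DRM2 (AT2G33830) rose from 397 ± 18.7 to 4142 ± 41.1 RPM (SD, n = 3), the glutamate dehydrogenase GDH2 (AT5G07440) from 63.7 ± 6.10 to 680 ± 21.4 RPM, and the hexose transporter STP1 (AT1G11260) from 95.5 ± 5.51 to 745 ± 17.7 RPM. Of 10 genes of branched-chain amino acid breakdown 9 rose (median 1.99, camera adjusted p = 1.54e-07, and adjusted p = 0.0206 with an estimated correlation), MCCA (AT1G03090) from 17.9 ± 1.25 to 162 ± 12.9 RPM and IVD (AT3G45300) from 14.2 ± 1.28 to 129 ± 3.72 RPM. Of 16 autophagy genes 13 rose (median 0.88, camera adjusted p = 1.22e-06, and adjusted p = 0.0206 with an estimated correlation), ATG8E (AT2G45170) from 43.3 ± 1.08 to 217 ± 33.4 RPM and ATG8H (AT3G06420) from 2.73 ± 0.522 to 21.8 ± 1.98 RPM. Of 6 sugar-induced genes 5 fell (GPT2, APL3, BAM5, APL4 and NIA1) and SUS3 rose (median -0.84, camera adjusted p = 0.0393, and adjusted p = 0.131 with an estimated correlation). Of 10 abscisic acid genes 6 rose and COR15A fell (7 and 2 without DEX-3, and 5 and 1 without DEX-1, DEX-2, DMSO-1 or DMSO-3, where COR47 did not pass, median 0.73, camera adjusted p = 0.0876), with the phosphatase ABI1 (AT4G26080) rising from 65.6 ± 1.40 to 237 ± 33.2 RPM.

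Most of the cutin, wax and early anther genes tested were lower in DEX. Of 14 cutin and wax genes 12 fell and none rose (median -1.05, camera adjusted p = 1.22e-06, and adjusted p = 0.104 with an estimated correlation), CER1 (AT1G02205) from 815 ± 36.9 to 344 ± 36.9 RPM and CYP86A4 (AT1G01600) from 152 ± 1.57 to 51.6 ± 10.0 RPM. The call of WIN1 (limma adjusted p = 0.0281) did not pass without DEX-3 (0.0820), DMSO-2 (0.0811) or DMSO-3 (0.121). It did not pass in limma without the intensity trend (0.142), with robust moderation (0.189) or with DESeq2 (0.221) either. Of 9 early anther cell fate genes EMS1, ROXY1, BAM1, BAM2 and SERK1 fell (median -0.55, camera adjusted p = 0.0104, and adjusted p = 0.104 with an estimated correlation), BAM2 (AT3G49670) from 91.3 ± 5.51 to 27.6 ± 3.96 RPM.

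The rise of ASN1, SEN1 and other dark-inducible genes was weighed against handling of the samples. Total-count scaling is argued against only as the source of the gap between these genes and the rest, since a factor shifts all genes of a library alike. The median log2 fold change over all genes was 0.0035, against 2.44 in the list of low-sugar inducible genes. Median-of-ratios factors of 0.989 to 1.006 moved almost no value (median log2 fold change of the 10 largest rises 5.0, and 5.01 as deposited). Factors this close to 1 change nothing, so rescaling could not decide the question. A difference in time of day between the groups stays open, because harvest times are not given in the sources used here and the clock genes do not decide it, with RVE1 up by 2.01 and PRR7 by 1.15, but at most 0.479 either way among CCA1, LHY, TOC1, GI, ELF4 and LUX. A low-sugar response in the DEX libraries is a candidate explanation, with a median of 2.44 and a range of 1.12 to 3.4 in the second list, but whether it may follow from ARF3-GR, from DEX itself or from light and handling was not tested.

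The rise of the 7 anther genes may come from older flowers left on the DEX inflorescences. Such flowers were predicted to raise the medians of a second tapetum list and of a list of 13 meiosis genes. This premise was itself not tested. MSH5 reaches 1 RPM in fewer than 3 DEX libraries and so is in the table because of its DMSO values, which favours genes that fell. With few members measured, the meiosis list does not decide the question. Its 4 measured meiosis genes had a median of -0.562 (SD over genes 0.437, camera adjusted p = 0.313), so the predicted rise was not seen. Of them SDS, MSH5 and ASY3 fell, the calls of SDS and MSH5 not passing without DEX-1 (adjusted p = 0.109 and 0.10), DEX-2 (0.0861 and 0.142), DMSO-1 (0.236 and 0.131) or DMSO-3 (0.050 and 0.144), nor with DESeq2 (0.0627 and 0.0798), edgeR (0.0507 and 0.0551) or a pseudocount of 0.1 (0.0569 and 0.0574), nor SDS with a replicate block (0.0524) or MSH5 with a pseudocount of 5 (0.0549). In the second tapetum list of 8 measured genes DRL1, MS2 and LTP12 rose and BHLH010 fell (median 0.04, camera adjusted p = 0.476). The predicted rise of this median was thus not seen either. The BHLH010 call did not pass without DEX-2 (adjusted p = 0.0608), DEX-3 (0.0562), DMSO-2 (0.0995) or DMSO-3 (0.112). MS2 had 0 reads in DMSO and so is in the table because of its DEX values, which favours genes that rose. MS2 already lies above the list median, so setting it to its bound could not move that median. A general rise of weak genes stays open: a share of 0.0013 of 10000 random lists matched on mean level had a median as high as 1.07, but such lists ignore that 5 of the 7 genes are in the table through their DEX values, and in 2 later tests with lists matched on that too the share was 0.0228 (genes nearest in mean) and 0.0459 (genes within 0.15 of the mean on the log2 scale), the latter near the threshold. A change of these genes with ARF3-GR or DEX stays open and untested.

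DNA replication genes fell more than mitotic genes, with medians of -1.75 over 6 and -0.41 over 10 genes of the fixed cell cycle list. Transcript length and GC content are argued against, since the difference was -1.33 before and -1.22 after correction for both. In second lists, 8 of 11 replication genes fell (median -1.08, camera adjusted p = 7.83e-05, and adjusted p = 0.0338 with an estimated correlation), while 7 of 12 mitosis genes fell and CYCB2;4 rose (median -0.43, camera adjusted p = 0.0613), a difference of -0.650 (permutation p = 0.00372 over genes, which are not independent). The CYCB2;4 call did not pass without DEX-2 (adjusted p = 0.0640) or DMSO-1 (adjusted p = 0.123). Among those that fell, the call of CDC20.2 did not pass without DEX-2 (limma adjusted p = 0.0553) or DMSO-1 (0.0811), nor in limma without the intensity trend (0.0507). A lower share of cells in S phase against mitosis is a candidate explanation, and a change of transcription without one stays open.

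The real split of the 6 libraries was the only 1 of 10 splits into 3 and 3 to call as many genes. It called 10204 by limma and 10146 by edgeR, and the others called at most 0 by either. At an unadjusted p under 0.05 the real split had 10918 genes with limma, and the others had at most 212 with limma and 211 with edgeR. Each other split mixes DMSO and DEX libraries in both groups, so the treatment difference adds to the spread within groups. Few calls were thus given in advance, and these counts do not measure a chance level. Such splits are also too few for a share under 0.05.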
